A study of Homo sapiens with 8 samples.

How the data were processed

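RNA recovered with biotinylated microRNA duplexes was sequenced from 786-0 cells, an established human line derived from a clear cell renal carcinoma. The 8 libraries fell into 3 groups by their titles: 3 with a control microRNA, 2 with miR-2355 and 3 with miR-1271. Per the labels' protocols, RNA was taken with TRIzol and a spin-column kit, concentrated, and made into libraries with a Takara SMARTer kit. Neither a sample of the RNA before the pulldown nor a measure of how much RNA was recovered was used here, so every value is a share of what was recovered, and a change in total recovery would not be seen. A changed level of an RNA in the cells cannot be told apart from a changed recovery either.

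The deposited values are raw read counts per gene, 1 column per library, with no normalization. The submitters' processing notes list BWA and featureCounts and the builds hg38 and GRCh38, without versions. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. BWA does not join reads across splice junctions, so reads that span them can be lost, and genes with many short exons can be counted low in all libraries alike. Without a known strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart, and rows for near-identical gene copies can share reads: among the 10 most abundant rows, 2 pairs differed by under 10% in every library.

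The table held 60666 Ensembl gene IDs, of which 22768 had no read in any library. The files do not pair these IDs with gene names, and none of the IDs matched the gene table used here (0 IDs matched), so the values are reported by ID and by group of genes, and no gene is named. The gene lists fixed by symbol before the data were examined and the planned test of seed matches in 3′ UTRs, which needs transcript sequences, were not run, nor was the planned fit on protein-coding genes only. GC content and gene length were not available for these IDs for the same reason, so no check of either was made.

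Total counts ran from 4122875 to 22864693 per library. The fits used edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr, which left 17351 genes and 99.78% to 99.82% of the reads of each library, libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 8 libraries so that the groups shared 1 estimate of the spread. Each of the 3 contrasts was tested with glmQLFTest, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called higher or lower. Standard errors were taken as the fold change divided by the square root of the F statistic. They are approximate and can be too small for rows with few reads in a group. Levels are TMM-scaled CPM, as mean ± SD over libraries. Where a gene had 1 to 3 reads in a whole group, the ratio of pooled reads is given with an exact 95% interval, and where it had none, a bound against 3 reads over the group's total; both cover counting error only, since reads without molecular identifiers are not independent molecules. The labels do not say whether libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical. They also give no batch or date.

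The rule for named genes, set before the data were examined, took the 12 largest rises and 10 largest falls per contrast with the control, and 5 of each for the direct contrast. It required an adjusted p under 0.05, a mean log2 CPM of at least 1, and every microRNA library beyond every control library. Its clauses on symbols, seed matches and gene lists could not be applied, and because the IDs have no names only 2 that rose and 2 that fell are printed, the first by the rule in each contrast with the control.

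A gene was called selective for a microRNA when it was higher both against the control and against the other microRNA, which makes the direct contrast the test of selectivity. Because both contrasts use the same controls, 20 data sets without group differences were simulated. All 8 libraries were drawn, the controls included, each gene independently around its mean in the real controls. After the data had been seen, 20 more were drawn over all genes with a read, around their pooled share in all libraries. The procedure was tested on simulated counts for the same 17351 genes, with 200 changed genes per contrast. For miR-2355 against control it recovered 19.4% of 1.5-fold, 65.7% of 2-fold and 84.9% of 4-fold changes, with 7.38% false calls among all calls. For miR-1271 against control it recovered 40.3%, 65.7% and 89.4%, with 9.72% false calls, and for the direct contrast 20.9%, 61.2% and 83.3%, with 9.84% false calls. Each false share lay above the 0.05 set for the adjusted p. The rates rest on 1 simulated data set per contrast with far fewer changed genes than the data called. They therefore do not give the rates of the contrasts reported here. Replicates were compared with a chi-square statistic over the tested genes: within groups it was 5.76 to 21.4 per degree of freedom. Values above 1 were to be expected of separate deep libraries, so this describes their spread and is no test of agreement.

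Alternatives set beforehand were DESeq2 1.42.0, other scaling factors, other filters, fits of only the groups compared, the replicate number as a block, other thresholds, and leaving out each library in turn. The replicate numbers showed no sign of pairing: deviations from the group means of equally numbered libraries correlated at -0.10 to 0.02. Unequally numbered ones correlated at -0.10 to 0.10. Deviations in groups of 2 or 3 libraries are bound to each other, so this cannot show that the numbers carry no pairing. Thinning to equal depth, leaving out the 30 most abundant rows, and lists of cell-cycle genes by Ensembl ID from scran 1.30.0, tested with camera in limma 3.58.1 at a preset correlation of 0.01, were added after the data had been seen.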

Results

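To find RNAs bound by miR-2355-5p and by miR-1271-5p in renal carcinoma cells, biotinylated duplexes of each were transfected into 786-0 cells and the RNA recovered with them was sequenced. Pulldowns with a control duplex served as the background. The control group held 3 libraries with 22864693, 4122875 and 20722317 counted reads. The miR-2355 group held 2 libraries with 18637410 and 14924700 reads, and the miR-1271 group held 3 with 10358878, 10959081 and 13119672 reads. The design text speaks of triplicates, but only 2 miR-2355 libraries were among those used. Between 21968 and 29840 gene IDs had at least 1 read per library, the fewest in control replicate 2, the shallowest library. Genes are given by Ensembl ID because the files do not pair the IDs with names.

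The libraries separated by group. The first principal component of log2 CPM, with 50.9% of the variance, placed the 3 control libraries between -70.8 and -37.9 and the 5 microRNA libraries between 13.03 and 42.3. The second, with 15.1%, placed the 2 miR-2355 libraries at -36.1 and -35.1 and the 3 miR-1271 libraries between 10.99 and 19.7. Pearson correlations across genes, which are not independent replicates, were 0.973 to 0.989 within groups and 0.938 to 0.981 between groups. A single gene row was the most abundant in all libraries and took 4.65% ± 0.11 (SD, n = 3) of control reads, 4.79% ± 0.39 (SD, n = 2) of miR-2355 reads and 7.22% ± 1.17 (SD, n = 3) of miR-1271 reads. The difference between miR-1271 and control had an exact permutation p of 0.1 (two-sided), the smallest that 3 against 3 libraries allow.

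**Figure D1:**
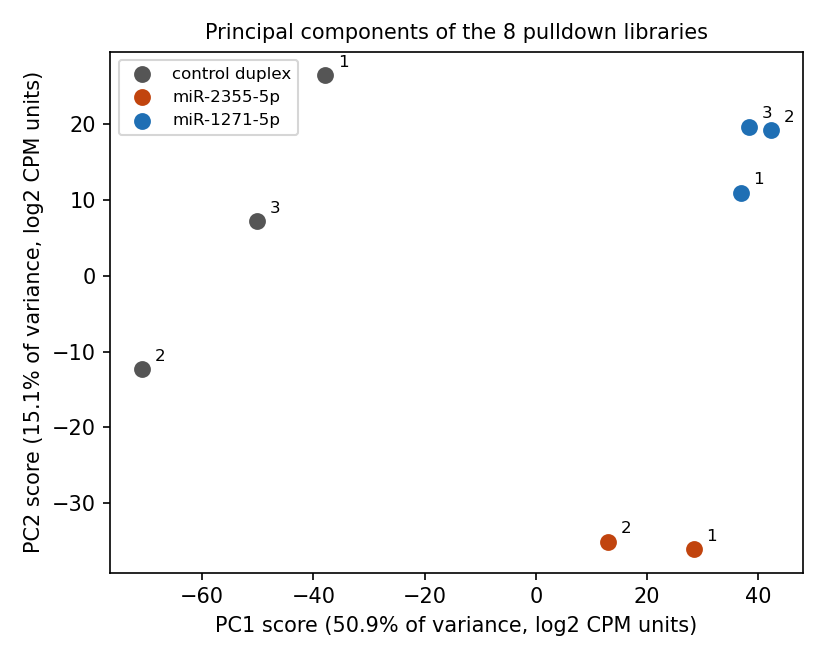
Scores of the 8 libraries on the first (x axis) and second (y axis) principal components of TMM-scaled log2 CPM, with points coloured by group and numbered by replicate. The 3 control libraries lie at or below -37.9 on the first component and the 5 microRNA libraries at or above 13.03, and the 2 miR-2355 libraries lie at -36.1 and -35.1 on the second.

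In the pulldown with miR-2355, 2127 of 17351 tested genes were higher and 3044 lower than with the control duplex (edgeR quasi-likelihood test, adjusted p under 0.05). The falls were larger than the rises: 1246 genes fell and 359 rose at least 2-fold, with median log2 fold changes of -0.88 among the lower genes and 0.61 among the higher ones. The largest rise was that of ENSG00000253008, at 60.2 ± 30.2 CPM (SD, n = 2) with miR-2355 against 0.030 ± 0.026 (SD, n = 3) with the control. Its reads numbered 1527 and 607 in the miR-2355 libraries and 1, 0 and 1 in the controls, a ratio of pooled read shares of 1517 (exact 95% interval 419 to 12530). The fitted log2 fold change was 10.26 with a standard error of 0.51 and an edgeR adjusted p of 5.36e-09. With so few control reads this standard error is too small. The exact interval is far wider, although it covers counting error only. The largest fall by the same rule was that of ENSG00000232060, from 4.02 ± 0.98 CPM (SD, n = 3) to 0.235 ± 0.030 (SD, n = 2), a log2 fold change of -4.08 ± 0.43 (SE; edgeR adjusted p = 3.14e-06). The 12 largest rises under the rule for named genes ran from 2.66 to 10.26 on the log2 scale and the 10 largest falls from -3.14 to -4.08. In all, 1915 of the higher and 2799 of the lower genes had a mean log2 CPM of at least 1 and every miR-2355 library beyond every control library. Over all tested genes, called or not, 52.7% showed no overlap between these groups, where chance gives 20%.

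The genes higher with miR-2355 made up 14.8% ± 0.09 (SD, n = 3) of control reads and 22.9% ± 1.4 (SD, n = 2) of miR-2355 reads, and the lower genes 21.4% ± 0.74 and 11.5% ± 1.3. These shares describe genes chosen on the same libraries and are not independent evidence. Calls of a rise were most frequent among abundant genes, where small changes can pass: 21.6% of the most abundant quintile of genes by mean log2 CPM and 4.49% of the least abundant quintile were higher. Rises of at least 2-fold ran the other way, with 154, 85, 46, 35 and 39 genes from the least to the most abundant quintile. In the least abundant quintile 154 of 156 called rises and all 190 called falls were at least 2-fold, so smaller changes hardly passed there. Calls of a fall were most frequent in the quintile next to the most abundant, at 24.01%, against 18.7% in the most abundant and 5.47% in the least abundant, and falls of at least 2-fold numbered 190, 340, 295, 241 and 180 in the same order. The scaling set the balance of directions. Higher genes made up 41.1% of the calls with TMM and 52.0% with upper-quartile factors. Without miR-2355 replicate 1, which leaves 1 library assumed to vary like the other groups, 760 genes were higher and 1569 lower.

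In the pulldown with miR-1271, 3062 genes were higher and 3910 lower than with the control duplex (edgeR adjusted p under 0.05). Again more genes fell than rose at least 2-fold, 1527 against 632. The median log2 fold change was -0.85 among the lower and 0.64 among the higher genes. The largest rise was that of ENSG00000221464, at 6.04 ± 2.79 CPM (SD, n = 3). Its reads numbered 38, 93 and 63 in the miR-1271 libraries and 0 in each control library, so that it was at least 89.6-fold higher against a floor of 3 reads over all control reads (edgeR adjusted p = 1.29e-06). The largest fall was that of ENSG00000198157, from 17.4 ± 4.1 CPM (SD, n = 3) with the control to 0.906 ± 0.122 (SD, n = 3), a log2 fold change of -4.27 ± 0.26 (SE; edgeR adjusted p = 8.8e-09). The 12 largest rises were at least 2.55 on the log2 scale, and the 10 largest falls ran from -3.26 to -4.27. Of the called genes, 2655 higher and 3501 lower ones had a mean log2 CPM of at least 1 and no overlap between miR-1271 and control libraries. Over all tested genes 49.9% showed no overlap, where chance gives 10%.

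The genes higher with miR-1271 made up 29.5% ± 1.2 (SD, n = 3) of control reads and 45.0% ± 1.9 (SD, n = 3) of miR-1271 reads, and the lower genes 25.4% ± 1.3 and 13.03% ± 0.63. Calls of a rise were again most frequent in the most abundant quintile, where 30.6% of genes were higher and 22.6% lower. In the least abundant quintile 7.35% were higher and 7.72% lower. Rises of at least 2-fold were most frequent there, with 245, 137, 64, 51 and 135 genes from the least to the most abundant quintile. Of the 255 rises called in the least abundant quintile, 245 were at least 2-fold, so smaller ones hardly passed there. Higher genes made up 43.9% of the calls with TMM, 54.6% with upper-quartile factors and 27.95% with library totals alone, which moved the median log2 fold change of all genes by -0.15.

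Against each other, the pulldowns differed in fewer genes than either did against the control: 608 genes were higher with miR-2355 and 459 higher with miR-1271 (edgeR adjusted p under 0.05), of which 163 and 138 differed at least 2-fold. With library totals alone in place of TMM these numbered 1252 and 261, and the selective genes given next 395 and 179, which reverses their order. Genes selective for miR-2355, higher than in both other groups, numbered 252. Their median log2 fold change against the control was 0.83 with miR-2355 and 0.00 with miR-1271, and they made up 1.496% ± 0.089 (SD, n = 3) of control, 2.72% ± 0.23 (SD, n = 2) of miR-2355 and 1.37% ± 0.03 (SD, n = 3) of miR-1271 reads. Genes selective for miR-1271 numbered 301, with medians of 0.91 with miR-1271 and 0.01 with miR-2355. They made up 2.62% ± 0.19 (SD, n = 3) of control, 2.90% ± 0.03 (SD, n = 2) of miR-2355 and 4.60% ± 0.24 (SD, n = 3) of miR-1271 reads. At least 2-fold in both contrasts, 58 genes were selective for miR-2355, all with no overlap between the miR-2355 libraries and the other 6, and 78 for miR-1271, 77 of them without overlap. These genes were called on the same libraries. Over all tested genes, 8.07% had both miR-2355 libraries above the other 6, and 9.68% had all miR-1271 libraries above the other 5. If all 8 libraries were alike, chance would give 3.57% and 1.79%. A shift of both microRNA groups away from the controls raises these shares without selectivity, so the excess does not measure selectivity.

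The row with the largest rise in each pulldown was also selective for it. Both rows could count the transfected duplex itself or RNA of its own locus. That was not tested, so neither is taken as an RNA bound by the microRNA. ENSG00000253008 had 0, 3 and 0 reads in the miR-1271 libraries and its ratio of pooled read shares between the pulldowns was 730 (exact 95% interval 249 to 3542; edgeR adjusted p = 2.6e-08). The fitted log2 difference of 9.22 ran from 8.56 to 12.85 on leaving out 1 library, the highest without miR-1271 replicate 2, which held all 3 reads. ENSG00000221464 had 0 reads in both miR-2355 libraries, so its share with miR-1271 was at least 63.0-fold higher (edgeR adjusted p = 7.28e-05). Of the rows that fell, ENSG00000198157 was lower with miR-1271 than with miR-2355 by a log2 difference of 1.39 ± 0.33 (SE; edgeR adjusted p = 0.0227, but 0.0711 to 0.117 without miR-1271 replicate 2 or 3 or either miR-2355 library), while ENSG00000232060 differed by -1.69 ± 0.54, which did not pass (edgeR adjusted p = 0.0755).

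The count of genes that differed between the pulldowns depended on single libraries. Genes higher and lower with miR-2355 numbered 154 and 70 without miR-2355 replicate 2, 305 and 253 without miR-2355 replicate 1, and 234 and 138 without miR-1271 replicate 3. They numbered 286 and 191 without miR-1271 replicate 2 and 395 and 263 without miR-1271 replicate 1. They numbered 915 and 785 without control replicate 1 and 485 and 365 without control replicate 3, and 697 genes were lower without control replicate 2. The controls do not enter this difference and can act on it only through the filter, the scaling and the shared estimate of the spread. A fit of the 2 microRNA groups alone gave 970 and 902. Genes selective for miR-2355 numbered 89 without miR-2355 replicate 2, 127 without miR-2355 replicate 1, 150 without miR-1271 replicate 2 and 129 without miR-1271 replicate 3. Genes selective for miR-1271 numbered 49 without miR-2355 replicate 2, 198, 136 and 115 without miR-1271 replicates 1, 2 and 3, and 540 without control replicate 1.

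Genes recovered with both microRNAs were the aim stated for the series. Higher in both pulldowns than with the control were 1369 genes, with median log2 fold changes of 0.61 for miR-2355 and 0.65 for miR-1271, and 124 of them rose at least 2-fold in both. Lower in both were 2563 genes, with medians of -0.92 and -0.98, of which 943 fell at least 2-fold in both. Only 27 genes were higher with miR-2355 and lower with miR-1271, and 6 the reverse, so 3932 of the 3965 genes called in both contrasts moved the same way. Over all tested genes the sign was the same for 78.3%, against 65.05% on average in the simulations of unchanged groups with shared simulated controls. Among abundant genes (mean log2 CPM of at least 6), 1 row rose most in both: it stood at 173 ± 29.9 CPM (SD, n = 3) in the controls, 4872 ± 359 (SD, n = 2) with miR-2355 and 6776 ± 2391 (SD, n = 3) with miR-1271, and the pulldowns did not differ in it detectably (log2 difference -0.48, edgeR adjusted p = 0.283). In the direct contrast, 6.28% of the genes higher in both and 3.63% of those lower in both differed between the microRNAs, against 6.15% of all tested genes.

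Both contrasts used the same 3 controls, which makes them agree in part without any effect. Independent lists of these sizes would share 375 higher and 686 lower genes. In 20 simulations of unchanged groups, both contrasts shared a simulated control group. Their fold changes correlated at 0.45 on average across genes, with a mean covariance of 0.032. The observed correlation was 0.75 and the observed covariance 0.377, a difference in covariance of 0.345. Without the low-count filter the correlation was 0.50 and with DESeq2, which kept all genes with a read, 0.52, against averages of 0.43 and 0.435 in 20 simulations fitted the same way, so the correlation exceeded that of unchanged groups by little once rare genes were included. The covariance was then 0.875 and 0.624, against simulated means of 0.534 and 0.352. The 3 controls cannot be split into groups of at least 2, so part of the excess may come from the shared controls. Without miR-2355 replicate 1, 481 genes were higher and 1458 lower in both, and without control replicate 3, 855 were higher in both.

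**Figure D2:**
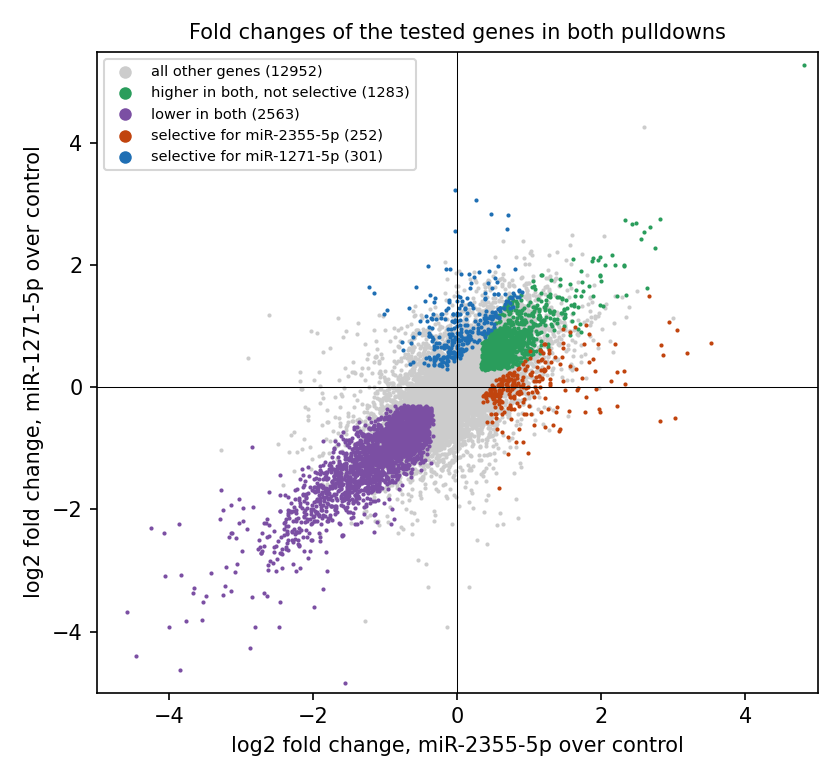
Log2 fold change over control with miR-2355-5p (x axis) and miR-1271-5p (y axis), 1 point per tested gene, coloured by class; genes that are both selective and higher in both pulldowns (30 for miR-2355, 56 for miR-1271) are drawn as selective, and 6 points lie outside the axes. Genes lower in both (2563) extend along the diagonal to below -4, and selective genes have medians near 0 for the other microRNA, with the middle 50% from -0.18 to 0.20 for those of miR-2355 and from -0.15 to 0.30 for those of miR-1271.

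**Figure D3:**
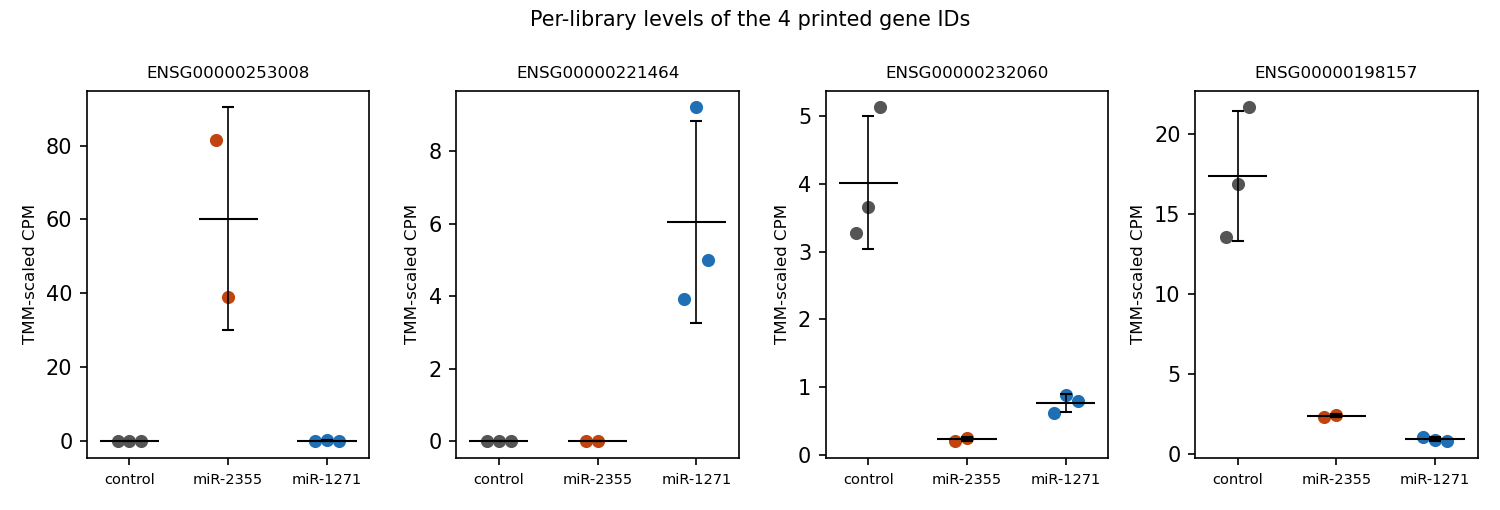
TMM-scaled CPM (linear y axes, each with its own range) of the 4 printed gene IDs by group (x axis), with 1 point per library and bars for the mean ± SD. ENSG00000253008 stands above 0.3 CPM in the 2 miR-2355 libraries alone and ENSG00000221464 above 0 in the 3 miR-1271 libraries alone, while ENSG00000232060 and ENSG00000198157 are highest in the controls.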

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

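The IDs in this part were picked because the difference between the effects of the 2 microRNAs was itself past the threshold in the direct contrast. The genes called in opposite directions were picked by those calls alone. The searches for rows with reads in a single group were chosen after such rows had been seen.

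ENSG00000253008 and ENSG00000221464 moved in 1 pulldown each, with differences between the microRNA effects of 9.22 and -9.45 on the log2 scale (miR-2355 minus miR-1271; the fitted sizes depend on the prior count, since the other groups hold 0 to 3 reads per library; they were 8.56 to 12.85 for the first on leaving out 1 library and -7.75 for the second at equal depth). A search over all rows found 1 row with at least 30 reads in each miR-2355 library and at most 3 in each other library, and 1 such row for the miR-1271 libraries; these are the 2 IDs named. No row met this for the control group, and 1 row did for the 5 microRNA libraries together. Of the 28 possible choices of 2 libraries and the 56 of 3, only 1 each, the real one, had such a row (0 in every other choice). This describes the rows and does not test chance, because the search was chosen after both rows had been seen. The rows stayed past the threshold without any 1 library, at log2 fold changes of 9.64 to 10.69 and 9.09 to 9.75 over control. A candidate explanation is that these rows count the transfected duplex itself or RNA of its own locus; this was not tested, because the IDs are not paired with names here.

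ENSG00000198157 fell in both pulldowns and further with miR-1271, with a difference of 1.39 on the log2 scale that did not pass at equal depth (1.42, edgeR adjusted p = 0.154) or without any 1 of 4 libraries (1.30 to 1.44, adjusted p 0.0711 to 0.117), so the size stayed and the call did not. Genes called in opposite directions numbered 27 for higher with miR-2355 and lower with miR-1271, and 6 for the reverse, and each of them differed in the direct contrast. Calls on opposite sides of the same controls make this nearly certain, so it adds no evidence.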

How the results depend on the processing

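Direction and significance of the 4 printed IDs held against the control under all alternatives run for them. In the direct contrast, rerun after the data had been seen, they held for ENSG00000253008 and ENSG00000221464. ENSG00000232060 passed there only with the threshold loosened to an adjusted p under 0.1 (log2 difference -1.69, edgeR adjusted p = 0.0755). ENSG00000198157 kept its size, at a log2 difference of 1.39, but did not pass with equal depth (1.42, edgeR adjusted p = 0.154), without miR-2355 replicate 1 (1.44, 0.0735) or 2 (1.35, 0.117), or without miR-1271 replicate 2 (1.39, 0.0711) or 3 (1.30, 0.095). All 10 counts of genes stayed within 1.5 times under DESeq2, median-of-ratios (RLE) or upper-quartile factors, the stricter filter, and the settings added later, equal depth and no 30 most abundant rows. Library totals alone gave 1896 genes higher with miR-1271, 1252 and 261 higher and lower in the direct contrast (miR-2355 over miR-1271), and 395 and 179 selective for miR-2355 and miR-1271. Without a low-count filter, 930 genes were higher in the direct contrast. With the replicate number as a block, although the numbers showed no sign of pairing, 320 and 217 differed directly and 149 and 166 were selective. The block moved no other count by over 1.5 times. Fitting only the groups compared gave 970 and 902 direct and 547 selective for miR-1271. An adjusted p under 0.1 gave 1056 and 949 direct and 433 and 584 selective. Asking for at least 2-fold left 359 higher and 1246 lower with miR-2355, 632 and 1527 with miR-1271, 163 and 138 direct, 124 and 943 higher and lower in both, and 58 and 78 selective. Leaving out 1 library at a time gave 760 to 2241 higher and 1569 to 3000 lower with miR-2355, 154 to 915 and 70 to 785 direct, 481 to 1433 and 1458 to 2533 higher and lower in both, and 89 to 351 and 49 to 540 selective for miR-2355 and miR-1271. The causes were not tested, except that fewer libraries, another threshold or a fold limit change the counts by construction. In the direct contrast, control libraries act only through the filter, the scaling and the shared estimate of the spread. The correlation of the 2 sets of fold changes, 0.75, was 0.52 with DESeq2, 0.50 without a filter and 0.60 without miR-2355 replicate 1; simulations of unchanged groups gave 0.45, and 0.435 and 0.43 with DESeq2 and without a filter. On the 17351 filtered genes alone the DESeq2 fold changes correlated at 0.755. The planned fit on protein-coding genes, the seed test and the fixed gene lists were not run for lack of gene names and sequences. At equal, lower depth, most calls against the control in the least abundant quintile were lost before any test, since only 11.85% (miR-2355) and 11.66% (miR-1271) of these genes passed the low-count filter; of the calls that were tested, 54.5% and 64.1% were made again in the next quintile and 92.0% and 94.6% in the most abundant.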

Other observations

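The tests on the cell-cycle lists, on unequal depth and on the abundant rows were chosen after the results they bear on had been seen.

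Genes of the cell cycle were followed by Ensembl ID through the marker pairs shipped with scran. Each gene was assigned to the phase in which its times as the higher partner most exceeded its times as the lower. Of 1187 tested cell-cycle genes, 161 rose and 308 fell with miR-2355, and 250 rose and 386 fell with miR-1271. With miR-2355 these were 13.56% and 25.95%, against 12.3% and 17.5% of all tested genes. With miR-1271 they were 21.06% and 32.52%, against 17.6% and 22.5%. Both directions were thus called more often than over all genes, and abundance was not matched. Among 427 genes of the G1 list, 41 rose and 112 fell with miR-2355 (median log2 fold change -0.10, camera adjusted p = 0.06). With miR-1271, 70 rose and 148 fell (median -0.16, camera adjusted p = 0.0189; adjusted p = 0.504 with an estimated correlation). The S list, also of 427 genes, had 69 higher and 105 lower with miR-2355 and 101 higher and 132 lower with miR-1271 (camera adjusted p = 0.398 and 0.338). The G2/M list of 333 genes had 51 higher and 91 lower with miR-2355 and 79 higher and 106 lower with miR-1271 (camera adjusted p = 0.129 and 0.0654). In the direct contrast, no list reached an adjusted p below 0.795. No list passed with an estimated correlation, and the G1 call with miR-1271 was also lost with the stricter filter (adjusted p = 0.0545), upper-quartile factors (0.0589) and equal depth (0.0617). Other calls were gained: G1 with miR-2355 passed with library totals alone (adjusted p = 0.0465), without a filter (0.000817) and without control replicate 1 (0.0119) or miR-2355 replicate 2 (0.0212). G2/M with miR-1271 passed with library totals alone (0.0149), without a filter (0.0117) and without control replicate 1 (0.0382), miR-2355 replicate 2 (0.0472) or miR-1271 replicate 3 (0.0369).

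The strongest pattern was that 3932 genes moved the same way with both microRNAs, against the same controls. Sampling of the shared controls, with each gene drawn independently, did not give it in simulation. For the filtered genes the observed covariance of the fold changes was 10.9 times the highest of 20 simulations. In these, at most 1 gene was called the same way in both. The limit set beforehand was more than 2 times. It was not met without the low-count filter, at 0.875 against at most 0.551, or with DESeq2, at 0.624 against at most 0.3625. The draws hold no variation shared across genes within a library, so such variation among the controls is not excluded. Unequal depth is argued against as the whole cause, by a limit set after the data had been seen. Of the 3932 genes, 2864 (72.8%) were called the same way again with all libraries thinned to the smallest total. Without the 30 most abundant rows, 3836 (97.6%) were. TMM already trims such rows from the scaling, so leaving them out could hardly change the calls, and this decides little about them. Also open is which side changed. RNAs that the control duplex itself recovers, a handling of the control libraries apart from the others, or a recovery shared by both microRNAs could each give equal changes in both contrasts, and the design places all of them between the same libraries, so they cannot be told apart here. Nor can a level changed in the cells be told apart from recovery, since no RNA from before the pulldown was used.

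For miR-1271 against control, 6972 genes were called, and the highest of the other 9 splits of the 6 libraries called 0 (edgeR; 557 genes at an unadjusted p under 0.05, against 8380 in the real split). The 10 splits are too few for a share under 0.05. Every other split also mixes control and miR-1271 libraries within a group, which puts any difference between them into the spread. Where the groups differ, such splits call few genes by construction, so their 0 calls are no measure of chance.

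Control replicate 2, the shallowest library, correlated with the other controls at 0.973 and 0.979, while these correlated with each other at 0.989. With all libraries thinned to its depth, the mean gap shrank from 0.0134 to 0.0029 ± 0.0003 (SD over 20 draws), which lies between the limits set for depth as the whole cause and for another cause. At that depth, controls 2 and 3 correlated at 0.981, as controls 1 and 3 did, and only controls 1 and 2 were lower, at 0.975. Shallow depth could therefore account for most of the gap. What remained at that depth lay between controls 1 and 2, and its cause stays open. Thinning adds noise to the deeper libraries, which can hide differences, so a trait of control 2 against both others is not excluded. No biological explanation was tested, since the 3 libraries carry the same label.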
